A study of Danio rerio with 6 samples.

How the data were processed

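RNA from pooled whole zebrafish embryos was labelled with biotin from 6 µg of total RNA and hybridised to 1-colour Affymetrix zebrafish arrays, per the labels' protocols. The table of the authors' deposited values holds log2 values, 1 per probe set and array, for 6 arrays: 3 of embryos in DMSO and 3 of embryos in 5 µM 11,12-EET. How the authors corrected the background, summarised the probes and scaled the arrays is not given in the sources used here, nor is the base of the logarithm. The base was settled from the values: the hybridisation controls rose by 0.94 per doubling of their concentration, where a natural log would give 0.69, and the highest value of 13.63, read as a natural log, would exceed the 65535 that the scanner can record. The values ran from -3.87 to 13.63, and 5.2% were below 0. No detection calls were used here, so a dim probe set could be tested without being known to be above background.

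Of 15617 probe sets, 115 controls were left out and 15502 were tested. Genes were named from the platform annotation given with the data: 10795 tested probe sets had 1 gene symbol, 135 several and 4572 none, and those with several or none carry no gene name here. Symbols were updated through Entrez identifiers and a RefSeq gene table of the GRCz12tu assembly, in which 10711 were matched and 1 symbol changed. The annotation names no genome build, so no coordinates are given. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stood for it, which gave 8793 genes.

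The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 2-sided, no covariates), with Benjamini-Hochberg adjustment over all 15502 probe sets and calls at an adjusted p under 0.05. Gene lists with at least 5 measured genes were tested with camera from limma at a preset correlation of 0.01, adjusted over the 32 lists tested. Beside it the correlation was estimated for each list, and fry was run. For lists the trend was set in camera, which has no robust setting, and trend and robust in fry. The standard errors are those of limma, taken from the fit to the brighter probe sets where the adjusted p comes from it or where that set is named. The comparison, the lists, the settings and the rule for named genes were fixed before the data were examined. By that rule the text names the genes with the smallest p in each direction, up to 8, where none passed, given as values and not as changes, list members that passed, and a fixed set of AP-1, blood and eicosanoid-related genes. Genes outside the rule are and1, and3, fn1b, mmp9, socs3a, socs3b, timp2b, hmgcs1, fdft1, insig1, cyp51, zdhhc18a, ddah1, cryaa and cfp, chosen after their values were seen.

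The procedure was tested on simulated data for this comparison, 10 times with 200 changed probe sets each. Over all 15502 probe sets 26.9% of 2-fold and 72.9% of 4-fold changes were recovered, and 5.67% of calls were false. Over the 7751 brighter probe sets 92.4% of 2-fold and 100% of 4-fold changes were recovered, and 5.81% of calls were false. A list shifted by 0.5, the sterol synthesis list, was recovered in 10 of 10 simulations, with 0 of 310 false lists. Each probe set was simulated independently, without correlation between genes and without the difference of replicate 3 described below. The simulation therefore does not show how many false lists or calls to expect in the real arrays. With fewer than 200 changed probe sets the Benjamini-Hochberg cutoff is stricter, so the recovered shares may be too high for the real arrays.

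Alternatives were quantile normalisation, median centring, filters on dim probe sets, log2(2^value + 32), eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, other thresholds, the mean of all probe sets of a gene, and other set tests. Because replicate 3 of both groups stood apart, fits with replicate 3 as a batch term and without both replicate 3 arrays were added after the data were seen. The count among the brighter probe sets was made a result of its own at the same time.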

Results

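Transcript levels were measured in pools of whole wild-type AB zebrafish embryos at 36 h post fertilisation. The embryos had been kept from 24 to 36 h in 5 µM 11,12-EET, an epoxide that cytochrome P450 enzymes make from arachidonic acid, or in its solvent DMSO. Each treatment had 3 arrays, and 25 embryos were used per treatment group. The labels call the arrays biological replicates but do not say whether they came from separate clutches. The limma p-values of single probe sets therefore measure the spread between these pools. The camera p-values with the preset correlation set a list against the spread over the other genes, so they do not measure the spread between pools. The 6 arrays were alike in scale, with medians of 4.81 to 4.82 on the log2 scale, and correlated with each other at 0.943 to 0.957 across probe sets. The number of arrays limits the precision, as does the level: the median SD between replicates was 0.982 in the dimmest 25% of probe sets and 0.145 among the brighter probe sets, the 7751 at or above the median level of 4.81. On the first principal component of the brighter probe sets, which held 44.0% of the variance, replicate 3 of both groups stood apart from the other 4 arrays, and the next component, with 19.6%, separated EET from DMSO.

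The comparison of EET with DMSO asked which transcripts differed after 12 h of exposure. Among the brighter probe sets, and2 was 2.61-fold lower in EET embryos, and c6.2, clu, fosl2, hmgcs1 and a probe set without a gene name were 1.79-fold to 2.86-fold higher. The gene and2 encodes an actinodin, a structural protein of the fibrils that hold the larval fin fold, c6.2 a complement component of the membrane attack complex, and clu the secreted chaperone clusterin. The gene fosl2 encodes a Fos family subunit of the transcription factor AP-1, and hmgcs1 an early enzyme of sterol synthesis. Over all 15502 probe sets, none of these passed: limma called 0 probe sets at an adjusted p under 0.05, the smallest adjusted p being 0.0513, while 817 (5.27%) had an unadjusted p under 0.05 where chance gives 775.1. Of these 817, 413 were higher and 404 lower in EET. In 1817 probe sets (11.7%) the levels of both groups did not overlap, where chance gives 10% for 3 against 3.

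The 6 probe sets were called by limma within the brighter probe sets, a filter planned before the data were examined but reported as a result of its own after the count over all probe sets had been seen to be 0. In this set 516 had an unadjusted p under 0.05. The level of and2 was 8.68 ± 0.12 (SD, n = 3) in DMSO and 7.29 ± 0.17 in EET, a log2 difference of -1.39 ± 0.12 (SE, adjusted p = 0.00994). The level of c6.2 was 5.05 ± 0.25 in DMSO and 6.47 ± 0.03 in EET, a difference of 1.41 ± 0.13 (adjusted p = 0.00994). For clu the difference was 1.52 ± 0.16 (adjusted p = 0.0205), for fosl2 0.97 ± 0.11 (adjusted p = 0.0323) and for hmgcs1 1.16 ± 0.15 (adjusted p = 0.0403). The probe set without a gene name differed by 0.84 ± 0.10 (adjusted p = 0.0374). All 6 separated the 3 EET arrays from the 3 DMSO arrays. Over all probe sets the adjusted p was 0.161 for and2, 0.240 for c6.2, 0.317 for clu, 0.326 for fosl2 and 0.522 for hmgcs1. With limma's trend and robust settings and2, c6.2 and clu passed over all probe sets (adjusted p = 0.0011, 0.0055 and 0.0066). In that fit fosl2 and hmgcs1 did not (0.0663 and 0.0527). With quantile normalisation or the replicate number as a block, 0 probe sets passed. With 1 array left out the differences stayed between -1.47 and -1.30 for and2, 1.27 and 1.49 for c6.2, 1.36 and 1.64 for clu, 0.89 and 1.03 for fosl2, and 1.01 and 1.27 for hmgcs1, while the number of calls fell in most of these smaller fits: 0 were left without DMSO replicate 1 or without EET replicate 2, 1 without DMSO replicate 2 or without EET replicate 1, and 2 without DMSO replicate 3, while 6, of which 5 were shared, were called without EET replicate 3. With both replicate 3 arrays left out 7 were called, all 6 among them and fn1b besides. With replicate 3 as a batch term 12 were called, all 6 among them, and the named genes gained were and1, and3, fn1b and insig1. With log2(2^value + 32) 8 were called, of which 4 were shared, and fosl2 was not among them, its difference being 0.47 on that scale.

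**Figure D1:**
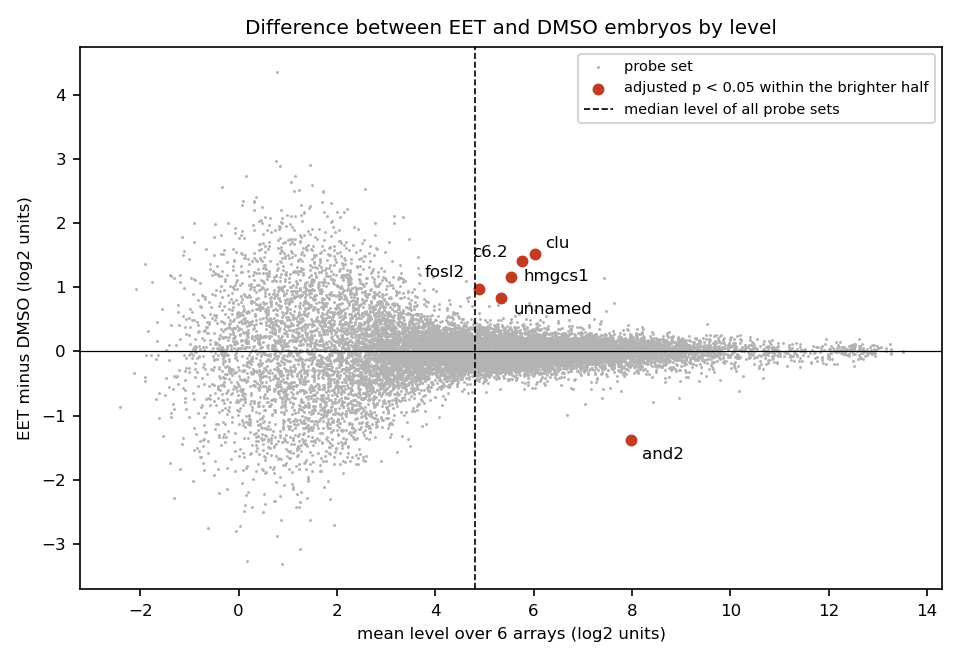
Difference between EET and DMSO in log2 units against the mean level over the 6 arrays, 1 point per probe set; the dashed line marks the median level of 4.81, and red points are the 6 called among the probe sets at or above it. Grey points spread widely at low levels, and and2 at -1.39 stands below the others at its level.

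The other actinodin genes, named here after their values were seen, lay on the same side as and2. The level of and1 was 9.31 ± 0.07 in DMSO and 8.59 ± 0.18 in EET, a log2 difference of -0.72 ± 0.12 (adjusted p = 0.140 among the brighter probe sets), and and3 differed by -0.999 ± 0.153 (adjusted p = 0.122). Both were lower in every EET array than in any DMSO array. Both were called among the brighter probe sets with replicate 3 as a batch term, with the replicate number as a block, with trend and robust, and with log2(2^value + 32). Neither was called there with quantile normalisation, median centring or array weights, without both replicate 3 arrays, or with any 1 array left out. In the pair of replicate 3 arrays alone the differences were -1.42 for and2, -0.83 for and1 and -1.23 for and3, and in the other 4 arrays -1.37, -0.67 and -0.88. The list of epidermal and wound genes, fixed before the data were examined, held and1 and and2. Of its 26 measured members 10 were higher and 16 lower, with a median of -0.05 (camera, adjusted p = 0.313). Adjusted over the list alone 4 members passed, against 0 over all probe sets: and1 and and2 on the lower side, and on the higher side fn1b, a fibronectin gene, and mmp9, a matrix metalloproteinase gene.

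Sterol synthesis genes were higher as a group. Of 11 measured members 10 were higher and 1 lower in EET, with a median log2 difference of 0.50 and a mean of 0.67 (camera with a preset correlation of 0.01, adjusted p = 7.85e-08). With the correlation estimated at -0.009, below the preset value, the adjusted p was 0.106. Over the other alternatives that used the preset correlation the adjusted p ranged from 1.36e-09 to 0.000144. With log2(2^value + 32), which compresses low levels, the median was 0.28. Adjusted over the list alone 4 members passed, against 0 over all probe sets. These were msmo1, a sterol demethylation enzyme gene (2.098 ± 0.233), hmgcs1 (1.16 ± 0.17), fdft1, which encodes squalene synthase (0.60 ± 0.12), and insig1, which encodes a sterol sensor of the endoplasmic reticulum (0.50 ± 0.13). All 3 probe sets of insig1 were higher in every EET array than in any DMSO array, at 0.50, 0.72 and 0.78. The lanosterol demethylase gene cyp51 had 4 probe sets, all higher in EET by group mean, and 0.96 ± 0.35 at the brightest, which differed by 1.34 without the replicate 3 arrays and by 0.19 in the replicate 3 pair. Without the replicate 3 arrays the list's median was 0.59 (adjusted p = 6.76e-07), and in the replicate 3 pair 0.42. An RNA quality control, the 3' minus 5' difference of actin, also lay apart between the groups, while that of GAPDH overlapped (values in the next paragraph).

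Inflammatory and NF-kB response genes were the other list shifted by camera. Of 20 measured members 17 were higher and 3 lower, with a median of 0.28 and a mean of 0.36 (adjusted p = 0.000199). With the correlation estimated at -0.012, below the preset value, the adjusted p was 0.142. With log2(2^value + 32) the median was 0.10. Adjusted over the list alone 2 members passed, against 0 over all probe sets: socs3b, a feedback inhibitor of cytokine signalling, at 1.09 ± 0.21, and mmp9 at 0.97 ± 0.21. The related socs3a differed by 0.80 ± 0.27 and timp2b, a metalloproteinase inhibitor gene, by 1.25 ± 0.50, without passing. In the replicate 3 pair socs3a differed by 0.11 and timp2b by 0.21. The list's median was 0.19 without the replicate 3 arrays (adjusted p = 0.00259) and 0.20 in the replicate 3 pair. A control of RNA quality lay apart between the groups for actin: the 3' minus 5' difference of the actin control probe sets was 1.74 to 2.01 in DMSO and 2.14 to 2.30 in EET, while for GAPDH it was 0.88 to 1.02 in DMSO and 0.94 to 1.27 in EET.

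**Figure D2:**
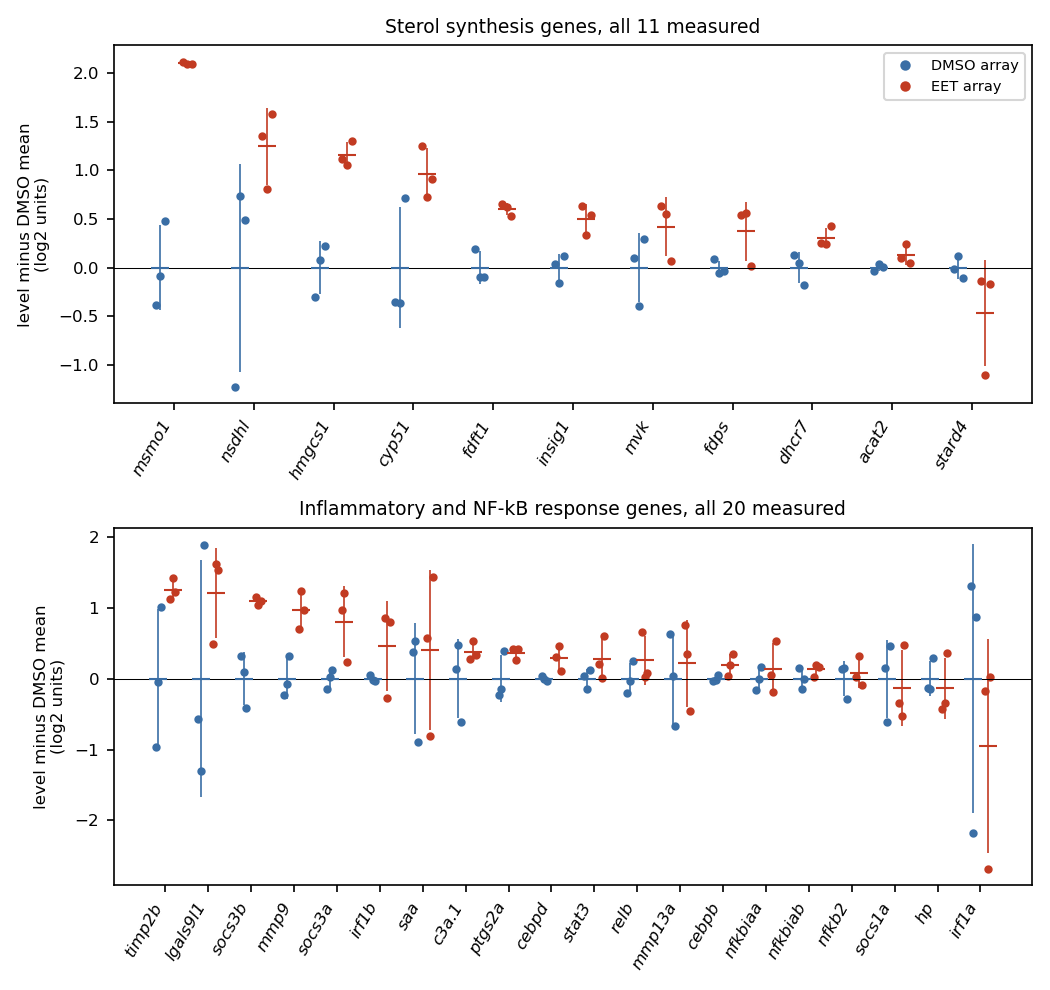
Level of each measured gene of the sterol synthesis list (top) and the inflammatory list (bottom) in log2 units minus its DMSO mean; points are arrays, horizontal ticks are group means and vertical bars are SD (n = 3). Of the sterol genes 10 of 11 and of the inflammatory genes 17 of 20 have a higher EET mean.

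AP-1 genes were followed because the family was fixed beforehand as a group of interest. Of 30 measured AP-1 and immediate early genes 19 were higher and 11 lower, with a median of 0.07 (adjusted p = 0.337), and without both replicate 3 arrays the median was 0.11 (adjusted p = 0.0493 with the preset correlation and 0.703 with an estimated correlation). In the replicate 3 pair it was -0.04, on the other side of 0, and with replicate 3 as a batch term the adjusted p was 0.306. Adjusted over the list alone 1 member passed, fosl2, against 0 over all probe sets. Its 3 probe sets differed by 0.97, 0.79 and 0.47. The Jun family genes junba and junbb differed by 0.70 ± 0.16 and 0.54 ± 0.15 and the stress-responsive atf3 by 0.55 ± 0.21, each higher in all 3 EET arrays without passing. For jun the difference was 0.08 ± 0.10. The 4 probe sets of fosab did not share a direction, lying between -0.12 and 0.34. The probe set with the highest mean level gave 0.34 ± 0.31. Its direction turned between batches: 0.77 without the replicate 3 arrays and -0.51 in the replicate 3 pair.

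No blood gene that was fixed beforehand passed the test. Of 15 measured haematopoietic stem and progenitor genes 8 were higher and 7 lower, with a median of 0.02 (adjusted p = 0.719). The stem cell regulator runx1 was near the lower end of the scale, at 0.43 ± 1.21 in DMSO and 1.64 ± 1.01 in EET, a difference of 1.21 ± 0.79. With 1 array left out the runx1 difference lay between 0.63 and 1.88. The transcription factor gene myb was better measured, and differed by 0.09 ± 0.13. The level of gata2a was lower in all EET arrays, by a log2 difference of -0.37 ± 0.09 (adjusted p = 0.554 among the brighter probe sets). The erythroid gata1a differed by 0.01 ± 0.16, lmo2 by 0.02 ± 0.33 and the myeloid spi1b by -0.06 ± 0.13 at its brighter probe set. The dimmer probe set of spi1b differed by -0.95 ± 0.47, lower in every EET array, without passing. Of 20 red blood cell genes 10 were higher and 10 lower, with a median of 0.00 (adjusted p = 0.973), and of 18 myeloid genes 13 were higher and 5 lower, with a median of 0.09 (adjusted p = 0.499). The probe set annotated to the xenobiotic response gene cyp1a differed by 0.29 ± 0.17, but it carries the same sequence cluster name as the probe sets annotated to mpx, a member of the myeloid list, so which gene each of these measures is uncertain. Of the genes fixed to be named, fosl1a, the jund genes, cxcl8a and ephx2 were not measured here.

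**Figure D3:**
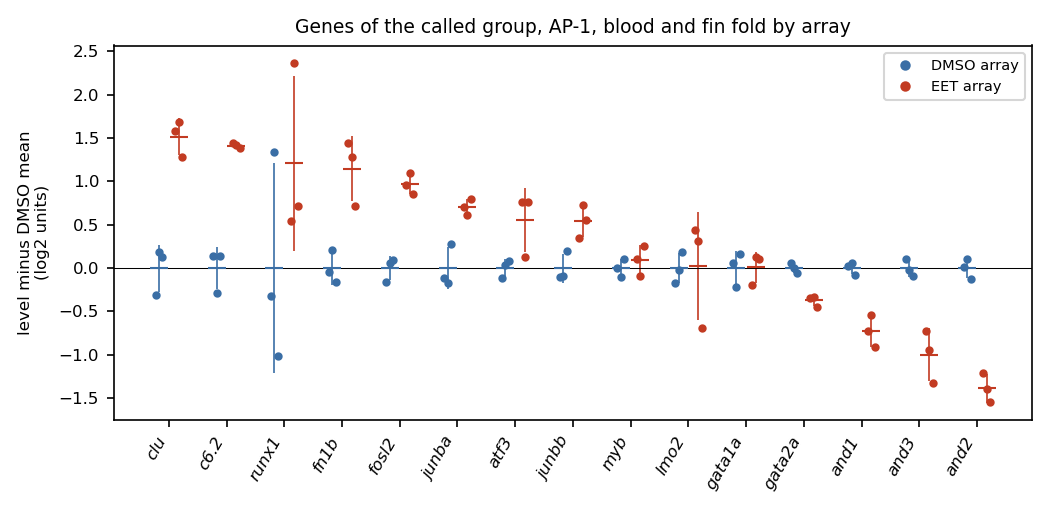
Level of 15 genes in log2 units minus the DMSO mean; points are arrays, horizontal ticks are group means and vertical bars are SD (n = 3). The EET arrays of and1, and2 and and3 lie below and those of fosl2, junba and junbb above all DMSO arrays, while those of myb, lmo2 and gata1a overlap them.

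Among all genes, those with the smallest p in each direction were mostly dim. On the higher side were asap1b (2.17 ± 0.18), zgc:193593 (1.88 ± 0.18), the chemokine gene ccl38a.5 (1.82 ± 0.17) and impa1 (2.73 ± 0.33), beside c6.2, msmo1, clu and fosl2. On the lower side, after and2, were wu:fk95d07 (-2.51 ± 0.28), lipt2 (-2.70 ± 0.31), dnajc24 (-1.37 ± 0.20), LOC100002469 (-0.78 ± 0.11), uckl1a (-2.42 ± 0.37), cfap100 (-0.67 ± 0.11) and si:ch73-14h10.2 (-0.92 ± 0.15). None of these passed over all probe sets. Group means below 0 on the log2 scale, as for zgc:193593 and impa1 in DMSO and wu:fk95d07 and uckl1a in EET, are not known to be above background. The smallest adjusted p, 0.0513, belonged to a dim probe set of zdhhc18a at -2.87 ± 0.15, a gene singled out after its values were seen, whose brightest probe set differed by 0.09 ± 0.20.

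Of 33 gene lists fixed before the data were examined, 32 had at least 5 measured genes and were tested, and 30 were not called, with medians from -0.08 to 0.26. Adjusted over the list alone 0 members of the lists that follow passed, and 0 over all probe sets. Genes of PPAR and fatty acid oxidation had a median of 0.20 (adjusted p = 0.0781), those of hypoxia and glycolysis 0.12 (0.150), exocrine and endocrine pancreas genes 0.26 (0.177) and cell cycle genes -0.06 (0.249). The PPAR list was called with a trend in camera, without the dimmest 25% of probe sets, without those below the median level, with log2(2^value + 32) and without DMSO replicate 2. The hypoxia list was called with a trend in camera, without DMSO replicate 1 and without EET replicate 3, and the pancreas list without DMSO replicate 1. With an estimated correlation none of these calls held: the adjusted p in the same settings was 0.260 to 0.523 for the PPAR, 0.574 to 0.758 for the hypoxia and 0.362 for the pancreas list. Medians were 0.06 for liver, yolk and gut (0.358), -0.05 for skeletal muscle (0.358), -0.08 for heart muscle (0.434), 0.00 for neural (0.541), -0.02 for eye and lens (0.973), -0.01 for pigment cell (0.908) and 0.02 for endothelial genes (0.885). They were 0.07 for xenobiotic and eicosanoid metabolism (0.541), 0.04 for oxidative stress (0.908), 0.02 for heat shock (0.973), -0.01 for unfolded protein stress (0.973) and 0.07 for p53 response genes (0.337). They were 0.04 for Notch (0.973), 0.02 for Wnt (0.973), -0.02 for PI3K and insulin signalling (0.973), 0.09 for chemokine and migration (0.434), 0.05 for circadian clock (0.719) and 0.00 for glucocorticoid response genes (0.973). Extracellular matrix genes had a median of -0.07 (0.566), ribosomal protein genes 0.03 (0.337) and mitochondrial respiration genes 0.03 (0.337). The 4 measured hatching gland genes were too few to test and had a median of 0.25. In 10 lists the median, the mean and the test differed in sign: haematopoietic, red blood cell, heat shock, unfolded protein, Notch, Wnt, pigment cell, glucocorticoid, PI3K and extracellular matrix genes.

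**Figure D4:**
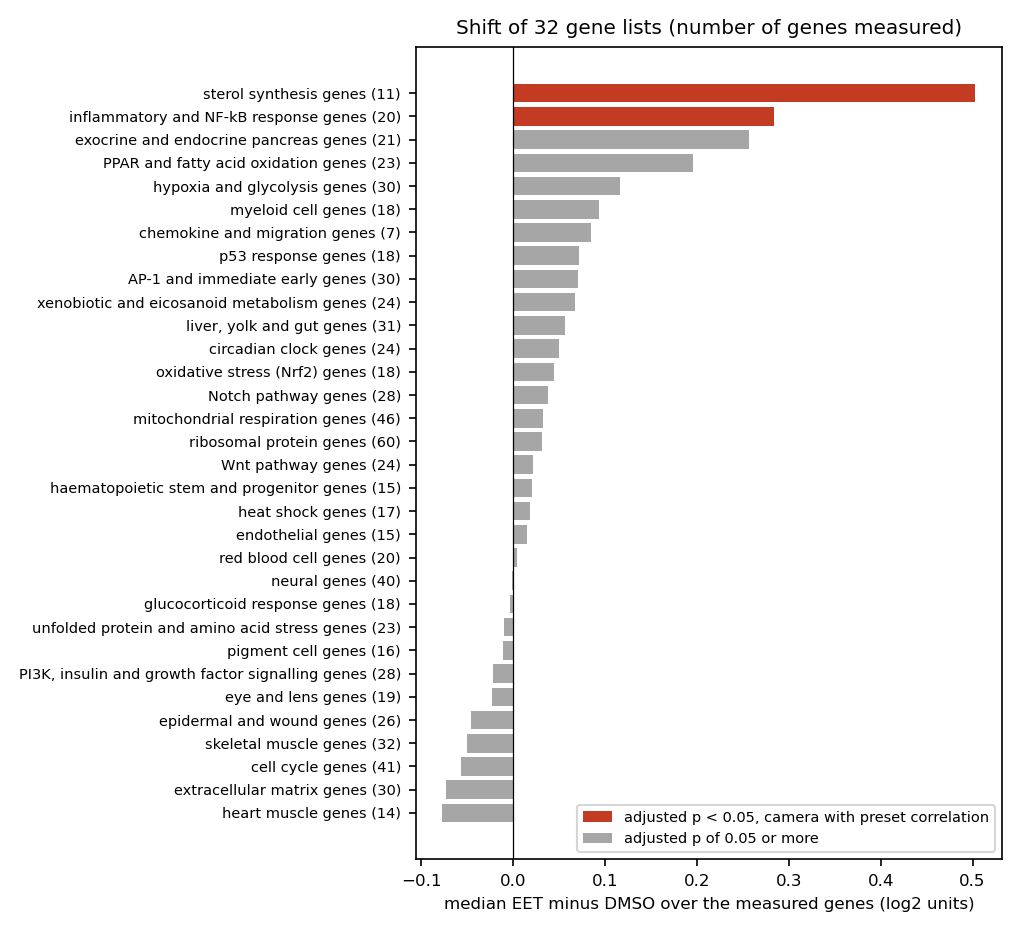
Median EET minus DMSO difference in log2 units of the 32 tested gene lists, with the number of measured genes in brackets; red bars are lists with adjusted p under 0.05 by camera with the preset correlation. The sterol list at 0.50 and the inflammatory list at 0.28 are the 2 red bars.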

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

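The fits with replicate 3 as a batch term or left out, and the count among the brighter probe sets as a result of its own, were chosen after the results were seen. Against 0 called over all probe sets, 1 was called after median centring, 1 with array weights and 1 at an adjusted p under 0.10, each lower in EET. Without probe sets below the median level 6 were called (5 higher, 1 lower). With log2(2^value + 32) 2 were called (c6.2 higher, and2 lower). With trend and robust 3 were called (c6.2 and clu higher, and2 lower). Quantile normalisation, the replicate block, the replicate 3 batch term, leaving out any array and leaving out the dimmest 25% gave 0. Centring hardly moved the values, since the array medians differed by 0.01, so it and quantile normalisation say little about stability.

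Among the brighter probe sets 6 were called, and 10 with trend and robust, 12 with the replicate block (and1, and3, fn1b and mmp9 among those gained), 12 with the replicate 3 batch term, 8 with log2(2^value + 32) (4 shared, fosl2 lost) and 0 to 6 with 1 array left out, where the differences of the 5 named genes stayed close to the full fit (and2 between -1.47 and -1.30). The replicate block left the count of lists at 2. Whether the numbers pair the arrays is unclear. Deviations of same-numbered arrays correlated at 0.042, 0.056 and 0.148 over all probe sets and at 0.177, 0.239 and 0.554 among the brighter ones, where replicates 1 and 2 correlated best with each other's number, and the fit without the block was kept. For 2 shifted lists the range with 1 array left out was 2 to 4, the lists gained being PPAR, hypoxia and pancreas genes, and the count was 0 with an estimated correlation and 1 with fry, which kept the sterol list. The medians of 0.284 for the inflammatory list and 0.503 for the sterol list are the same under these, and 0.101 and 0.276 with log2(2^value + 32). The inflammatory list no longer passed with the estimated correlation or with fry, and the sterol list not with the estimated correlation. That correlation was -0.012 for the inflammatory and -0.009 for the sterol list, both below the preset 0.01. A stronger correlation among members is therefore not what undid the calls with the estimated correlation. In that setting camera judges a list on the 4 residual degrees of freedom of the arrays. With a preset correlation it uses the far larger number of genes instead. The calls at the preset correlation therefore rest on the count of genes rather than on that of arrays. No other cause was tested. Camera with trend shifted 4 lists (PPAR and hypoxia genes gained) and fry with trend and robust 1, the sterol list, with the inflammatory list at an adjusted p of 0.0542; both settings were added after the results were seen.

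For 39 named genes 629 alternatives were computed, of which 611 kept direction and side of the threshold, 10 passed the threshold and 8 turned direction. With 1 array left out gata1a lay between -0.097 and 0.115, lmo2 between -0.188 and 0.378 and spi1b between -0.153 and 0.024, and spi1b was 0.008 without both replicate 3 arrays. The cause was not tested. The spread depended on level: the median SD between replicates was 1.13 in the dimmest 10% and 0.107 in the brightest 10%.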

Other observations

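Tests of the sterol genes, of younger embryos, of RNA degradation, of a trend of level and of other parents were chosen after the results were seen, and the fin fold, fin regeneration and complement lists were written after the main comparison but before their own tests. More probe sets were called between replicate 3 and the others than between EET and DMSO. The grouping by replicate 3 was picked because these arrays stood apart in the same values. Its counts and p-values are therefore selected and cannot be weighed like those of EET against DMSO. Among the brighter probe sets 304 were called between replicate 3 and the other replicates, 142 higher and 162 lower in replicate 3. The gene ddah1, which encodes an enzyme that breaks down methylarginines, was lower in both replicate 3 arrays (-0.45 in DMSO and -0.10 in EET, against 5.89 to 6.25 in the others), and a probe set without a gene name was higher (10.03 and 10.22, against 3.03 to 3.48), with an adjusted p of 0.0088 for both over all probe sets. The values of ddah1 in replicate 3 are not known to be above background, so no fold is given. The lens gene cryaa was lower by a log2 difference of -2.56 ± 0.18 and the complement regulator gene cfp higher by 2.85 ± 0.17, without passing over all probe sets (adjusted p = 0.0748 for both). Heat shock genes were higher in replicate 3 by a median of 0.27 (adjusted p = 0.0418), with an adjusted p of 0.835 with an estimated correlation.

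Because c6.2 and clu both act on the terminal complement pathway, a joint shift of complement genes was tested. Without c6.2 and clu the measured complement genes had a median of 0.086 (95% bootstrap interval -0.052 to 0.150), and camera gave no joint shift (unadjusted p of 0.291 across genes). The bootstrap intervals, here and below, resample the genes of a list and not the arrays, so they hold no spread between arrays. The bound set beforehand, a p of 0.05 or more, was a poor one, since a p that misses the threshold does not exclude a shift as small as the interval allows, so a small joint shift stays open.

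Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Over all probe sets the real split gave 0 and the highest other 1, so 10 of 10 splits gave as many. Among the brighter probe sets the real split gave 6 and the highest other 0, so 1 of 10 did. For lists the real split gave 2 and the highest other 3, so 2 of 10 did. The split with 3 lists put both replicate 3 arrays on the same side. However, the other splits that did so gave 0 lists, and 1 split that parted these arrays gave 1. Replicate 3 alone therefore does not account for the lists shifted in other splits. With both replicate 3 arrays left out the sterol list had an adjusted p of 6.76e-07 and the inflammatory list 0.00259.

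Whether the higher sterol synthesis genes may be an effect of EET is a hypothesis from these data. The tables argue against noise of dim probe sets, since the 6 members among the brighter probe sets had a median of 0.437 (95% bootstrap interval 0.218 to 0.882). The filter used the mean over both groups, however, and fdft1, at 4.581 in DMSO and 5.185 in EET, entered through its EET level. The tables also argue against a shift that rests on the replicate 3 pair, without which the median was 0.594. An offset shared by both replicate 3 arrays cancels from EET minus DMSO by design, so it was not tested. Within these arrays the values also argue against more liver, yolk and gut RNA. That list had a median of 0.056 (interval 0.012 to 0.140), under the lower bound of 0.307 for the sterol list. Both intervals treat the genes of a list as independent, so they compare lists on the same arrays and not EET with DMSO pools. RNA quality stays open, since the actin control differed between the groups, and the call was lost with an estimated correlation.

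The lower and1, and2 and and3 may be a change in the fin fold. Whether there was less fin fold tissue stays open. In all, 14 other fin fold genes had a median of 0.037 (interval -0.077 to 0.191). However, several of these are also expressed elsewhere in the embryo, so their level in whole embryos could hold while fin fold tissue was lost. Younger embryos stay open: 35 lens, eye and pigment genes had a median of -0.019 (interval -0.085 to 0.031), and without a series of ages a small delay cannot be excluded. A fin injury or regeneration response also stays open, since other fin regeneration genes had a median of 0.050 (interval -0.053 to 0.141).

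For replicate 3 of both groups, a scaling difference would move probe sets of like level the same way. The deposited arrays had nearly the same quartiles, so little overall difference of scale was left in them. In each of 5 bands of level at least 41.5% of the calls between replicate 3 and the others lay in the rarer direction. Quantile and loess normalisation left 44.0% of the variance on the first component but moved the values by a mean of only 0.014. With such quartiles both tests could hardly have come out otherwise, so they decide nothing. An effect of scaling before the authors' processing stays open. RNA degradation stays open: of the 4 actin and GAPDH values of the 3' minus 5' difference in replicate 3 arrays, 2 were the lowest of their own group and 0 the highest. Other parents or another clutch, a biological explanation, also stays open: 1 probe set among the brighter ones parted these 2 arrays from the others by 8-fold or more, and 0 did so for any other pairing of a DMSO and an EET array, and the rule that counts this small decide nothing was added after the count was seen. The count left out probe sets with a mean under the median level, ddah1 among them, so it may understate how many part these arrays.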
